A study of Mus musculus with 4 samples.

How the data were processed

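Single-cell RNA-seq was carried out on dispersed pancreatic islet cells of mice aged 5 weeks. Per the labels, 2 samples came from mice in which Xbp1 was deleted in beta cells after tamoxifen, and 2 came from mice with the floxed allele, which also received tamoxifen. Islets were hand-picked, kept in culture overnight and dissociated before 10x library preparation, per the labels' protocols.

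The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell. Per the file headers and the submitters' processing notes, the authors made them with Cell Ranger 6.1.2, and the notes name the build mm10. The annotation is not given in the sources used here. All 66890401 entries of the pooled matrix were whole numbers of at least 1, over 32285 genes and 19987 barcodes. Each barcode carries a number from 1 to 4, taken here as its library. No title, description or source name of a sample equals one of these numbers (0 of 4), so no library could be tied to a sample or a genotype. The comparison of genotypes was therefore not made, no test between libraries was run and no p-value is given. Each library's own value is given instead, and library numbers carry no order. Of the feature identifiers, 32158 (99.6%) were found in GENCODE M21, from which GRCm38 coordinates were taken.

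Cells were kept with at least 500 detected genes and at most 20% mitochondrial UMIs, which left 16146 cells. Scrublet, as run by scanpy 1.11.5 with an expected doublet share of 6%, marked 55 cells (0.341%), so the caller did not work. These 55 cells were removed as planned, which left 16091, and doublets otherwise remain. Clusters with at least 2 of Ins2 at 10% of UMIs or more and Gcg or Sst at 2% or more, summed over all libraries, stayed unnamed, which left cluster 3 among beta-like cells at 1.90% of UMIs from Gcg. Cells with at least 2 of Ins2 at 5% of UMIs or more and Gcg or Sst at 1% or more, 1036 cells (6.44%), were left out in an alternative chosen after seeing the data. The other added alternative left out the 6% of cells with the highest doublet scores in each library.

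Counts per cell were scaled to 10000 and log-transformed. From 2000 highly variable genes chosen by library, members of the fixed gene lists that were not markers and mitochondrial genes were removed, which left 1937. Clustering used 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). A cluster was named from fixed markers when at least 3 markers of a class reached 20 CPM and 3 times the median cluster, or 10% of UMIs. The naming rule, including the exclusions for clusters led by plasma cell, mast cell or proliferation genes, was written after the clusters were seen. The markers were fixed before the data were examined, as were the 16 gene lists and the rule for named genes.

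UMIs were summed per class and library and divided by the class total to give CPM. Ratios between classes were log2 ratios of CPM with a pseudocount of 10, taken within each library, for classes with at least 50 cells in every library. These were beta-like, alpha-like, delta-like and endothelial-like cells. A list's value was the median over members with at least 10 UMIs in either class, set against 10000 random lists matched on mean expression in 20 bins. Named list members were up to 4 per list with the largest ratio among those with the same sign in every library and at least 50 UMIs in a class. Between beta-like and alpha-like cells, 12 genes each way were named that were neither used for clustering nor markers. Between libraries, the 20 genes with the widest range in beta-like cells were named, at 100 CPM or more in a library and no marker of another class, with the same pseudocount of 10. Intervals are exact at the 95% level, Poisson for counts and Clopper-Pearson for shares, and cover counting error only. A count of 0 allows up to 3 counts. Ddit3 carries 2 identifiers, of which the one with 47883 UMIs was used.

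The ratio step was tested on simulated counts of 5865 genes. The median log2 ratio of 100 doubled genes was 0.90 with 0.86 expected under the pseudocount, and that of 100 halved genes was -0.78 with -0.77 expected. Of 200 unchanged lists, 4.5% fell outside the middle 95% of random lists. Both simulated classes had the same starting profile, with equal hormone shares and counting error only. The simulation therefore does not calibrate the percentiles of measured lists, whose classes differ in hormone share.

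Library totals were 82963911, 178396311, 85266513 and 110800927 UMIs for libraries 1 to 4, and the filter removed 12.0%, 29.7%, 13.8% and 13.1% of their barcodes. Alternatives were a stricter cell filter (1000 genes and 10% mitochondrial UMIs), called doublets kept, Leiden resolution 0.5, 7 hormone genes left out of the total, the mean of each cell's CPM, a pseudocount of 1, no filter on low counts and leaving out each library.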

Results

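The study set out to describe which genes depend on Xbp1, a transcription factor of the unfolded protein response, in beta cells of NOD mice. The pooled matrix held 4 libraries with 3627, 5265, 3415 and 3784 cells after filtering, at a median of 13287, 33052, 15759 and 27499 UMIs per cell before called doublets were removed. The labels name 2 groups of 2 samples, but the library numbers are not tied to them, so every value below belongs to a numbered library and none to a genotype.

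Beta-like, alpha-like and delta-like cells were found in every library, beside ductal-like, endothelial-like, fibroblast-like and immune cells. Beta-like cells made up 15.6% of library 1 (95% interval 14.4 to 16.8%), 60.6% of library 2 (59.3 to 61.9%), 20.9% of library 3 (19.6 to 22.3%) and 57.8% of library 4 (56.2 to 59.4%). B cell-like cells made up 18.5% (17.2 to 19.8%), 0.589% (0.400 to 0.835%), 14.99% (13.8 to 16.2%) and 0.0264% (0.000669 to 0.147%) of libraries 1 to 4, the last being 1 cell. Ductal-like cells took 17.9%, 0.551%, 9.25% and 0.264%, and T cell-like cells 5.32%, 1.48%, 4.42% and 0.291%. Acinar-like cells numbered 49 in library 1 and 11 in library 3. There were 0 in library 2 and in library 4, which allows up to 0.0570% and 0.0793%. Islets were hand-picked, which can set shares of cells from outside the islet. Cluster 2 held 65.3% of the beta-like cells in library 1 and 64.5% in library 3, but 0 cells of library 2 and 4 of library 4. Cluster 16 held 45.5% in library 2 and 30.9% in library 4. Against all other cells, the leading genes of cluster 2 held the alpha marker Ttr and those of cluster 18 the neutrophil marker S100a9. No beta marker was in either, but these other cells include the remaining beta-like cells. Against cells outside the class, the leading genes of cluster 2 held the beta markers G6pc2, Mafa and Ins1. Those of cluster 18 held Ins1, Ins2, G6pc2 and Mafa. The ductal marker Spp1, not among these leading genes, stood at 18013 and 14641 CPM in cluster 2 of libraries 1 and 3. In cluster 3 of the same libraries it stood at 1405 and 1279 CPM. Xbp1 is also given by cluster.

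**Figure D1:**
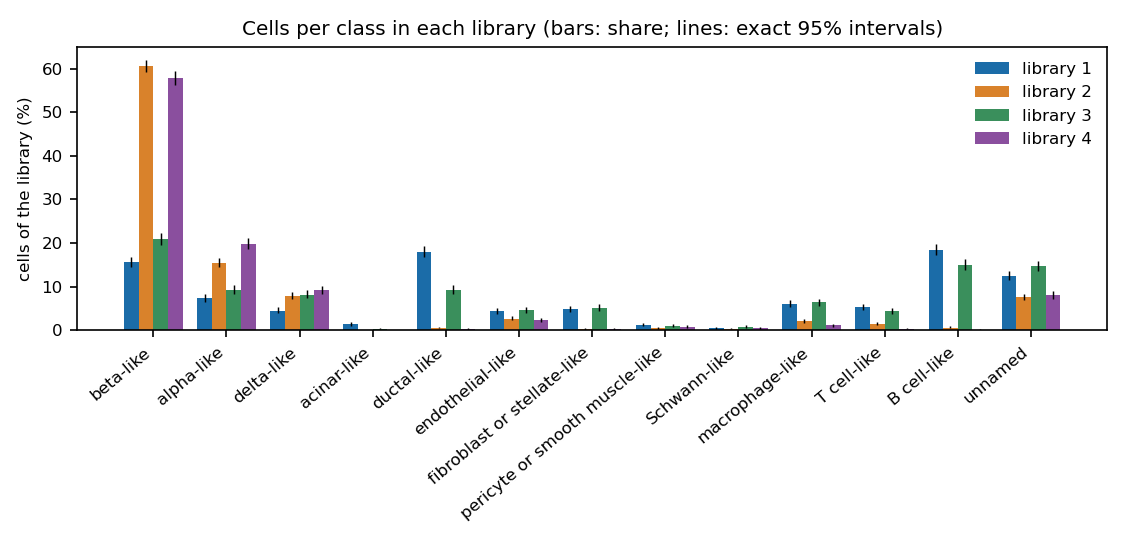
Bars give the share of each library's cells (%) in each class, and lines give exact 95% intervals for counting error. Beta-like cells range from 15.6% in library 1 to 60.6% in library 2.

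Xbp1, the gene targeted in the study (ENSMUSG00000020484, GRCm38 chromosome 11, 5520659 to 5525893, plus strand), was measured in every library. In beta-like cells it stood at 45.7 CPM in library 1 (95% interval 43.0 to 48.4), 95.1 in library 2 (93.5 to 96.7), 41.4 in library 3 (39.2 to 43.6) and 96.5 in library 4 (94.4 to 98.6). With hormone genes left out of the total, the levels were 77.3, 226.6, 69.6 and 222.5 CPM. By cluster, cluster 2 held 29.1 CPM in library 1 and 29.8 in library 3, cluster 3 held 76.4, 107, 68.3 and 105 CPM in libraries 1 to 4, and cluster 16 held 95.8, 95.9, 67.7 and 96.5. Gcg in cluster 3 stood at 2889, 41916, 3523 and 39977 CPM, which in libraries 2 and 4 is above the 2% of UMIs used to leave clusters with several hormones unnamed. Cluster 18 held 99.2 CPM in library 2 and 102 in library 4. Alpha-like cells held 134, 117, 131 and 118 CPM, and delta-like cells 158, 168, 152 and 158 CPM. Endothelial-like cells held 289, 115, 318 and 98.7 CPM. The labels give neither the deleted part of the gene nor which transcript end was read, and a UMI can come from a transcript that lacks an internal part, so these levels do not check the deletion.

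**Figure D2:**
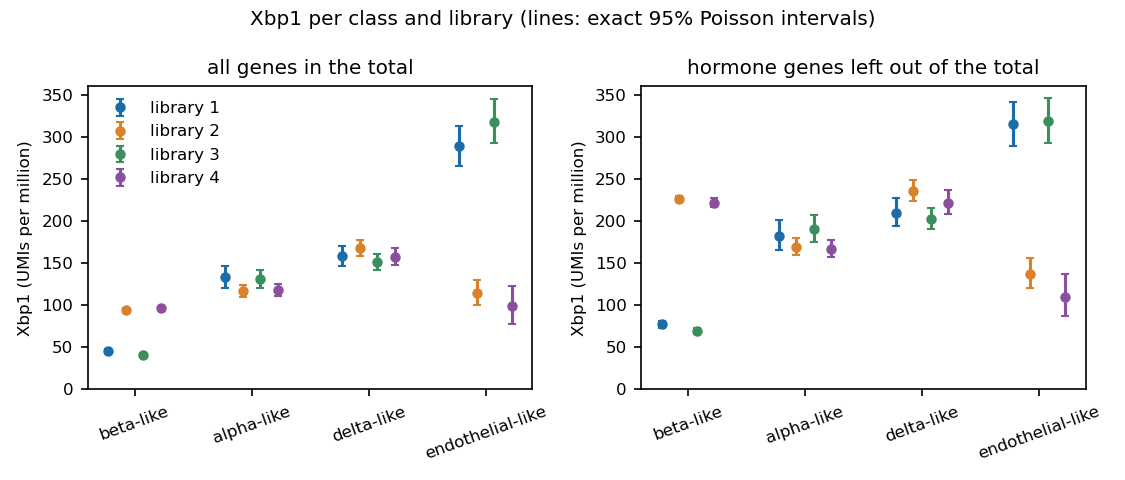
Points give Xbp1 in CPM for each class and library, with all genes (left) or without hormone genes (right) in the total, and lines give exact 95% Poisson intervals. Beta-like cells range from 41.4 in library 3 to 96.5 in library 4 with all genes in the total.

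Within each library, beta-like cells were compared with alpha-like, delta-like and endothelial-like cells. Genes of the PERK and ATF4 response, which raise amino acid supply and stress transcription, were higher in beta-like than in alpha-like cells. The list's median log2 ratio was 0.99, 0.97, 0.88 and 0.89 in libraries 1 to 4, above 100% of random lists in each. Of its 25 measured members, 20 were higher and 1 lower in every library. Nupr1 had a median log2 ratio of 3.68, Trib3 of 2.45, Atf5 of 2.30 and Cebpb of 2.08. Against delta-like cells the list's median was -0.10, and it was 0.37 with hormone genes left out. It lay there at percentiles 96.6, 100, 94.7 and 100 of random lists in libraries 1 to 4. In every library 7 members were higher and 12 lower than in delta-like cells, or 13 and 1 without hormone genes. Against endothelial-like cells the median was 0.29, at percentile 100 in each library, with 14 members higher and 8 lower in every library.

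Insulin and other hormone transcripts took 40.9%, 58.0%, 40.6% and 56.6% of the UMIs of beta-like cells, which lowers the CPM of every other gene. The median gene was shifted by -0.26, -0.56, -0.16 and -0.58 log2 units between beta-like and alpha-like cells, and by -0.01, -0.01, 0.01 and -0.05 with hormone genes left out. The medians over libraries of the secretory lists against alpha-like cells turned with this choice, but not every library did. ER chaperones and folding had a median log2 ratio of -0.29 (libraries 1 to 4: -0.39, -0.18, -0.41 and -0.15), and 0.21 without hormone genes, where libraries 1 to 4 had -0.10, 0.52, -0.22 and 0.53. ER translocation and signal peptide processing had -0.14 and 0.29, with -0.02, 0.56, 0.06 and 0.51 in the libraries without hormone genes. ER to Golgi transport had -0.30 and 0.13, with -0.10, 0.44, -0.22 and 0.37. Within these lists, the oxidase Ero1lb was higher in beta-like cells by 2.60, and Txndc5 (-1.18) and the translocon subunit Sec61a1 (-1.13) were lower, under both scalings.

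The lists of ER-associated degradation, UPR sensors and RIDD substrates had medians of -0.02, -0.30 and -0.07 against alpha-like cells, and 0.43, 0.02 and -0.02 without hormone genes. UPR sensors then had -0.22, 0.40, -0.32 and 0.25 in libraries 1 to 4. With all genes in the total, ER-associated degradation had 0.04, -0.13, 0.20 and -0.08, and of its 19 measured members 8 were higher and 6 lower in every library, or 11 and 3 without hormone genes. Edem1 (1.33), Herpud1 (0.99) and Derl1 (0.80), which act in disposal of misfolded proteins, were higher in beta-like cells in every library, and Vcp (-0.74) was lower. Against delta-like cells, 20 of 22 chaperone genes and 21 of 23 translocation genes were lower in beta-like cells in every library, with medians of -0.87 and -0.75. The median gene was itself shifted by -0.30, -0.59, -0.26 and -0.56 in libraries 1 to 4. Among random lists, chaperones lay at percentiles 0, 17.6, 0 and 5.8, and translocation genes at 0.4, 10.8, 0.16 and 5.5. Without hormone genes the list medians were -0.37 and -0.28, and 13 of 22 and 15 of 23 members were lower in every library. In libraries 1 to 4 chaperones then had -0.59, -0.07, -0.70 and -0.15, and translocation genes -0.36, -0.12, -0.46 and -0.19. The ER chaperones Fkbp2 (-1.60) and Pdia3 (-1.56) and the translocon-associated Ssr2 (-1.51) were among the named members. Ero1lb went the other way and was higher in beta-like cells (3.81). The immediate early list was also lower than in delta-like cells (median -1.93), led by Egr1 (-3.23) and Atf3 (-2.85).

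Outside the clustering genes and markers, the prohormone convertase Pcsk1 (4.39), Npy (3.83), Igf1r (3.47), Prss53 (3.38), Glp1r, the receptor of an incretin (3.21), and Hadh (3.15) were higher in beta-like than alpha-like cells. Kcnk3 (-3.41), Itpr1 (-3.19), Gnas (-3.15), Tnr (-2.88) and Ncam2 (-2.82) were lower. These are medians over libraries. Npy ranged widely around its median, at 6.29, 2.31, 5.21 and 2.45 in libraries 1 to 4, and Pcsk1 had 4.97, 3.64, 4.78 and 4.00. Alpha-like cells came from cluster 10, with 1776 cells and a median of 3.33% mitochondrial UMIs, and cluster 14, with 370 cells, 11.5% and a median of 1308 genes, and Gm42418 stood at 14500.1, 15901, 15499 and 22054 CPM in alpha-like and 2248, 2456, 1760.2 and 4108 CPM in beta-like cells of libraries 1 to 4. Whether RNA quality adds to the ratios of the named genes was not tested. Beta-cell identity genes had a median of 2.41, as their markers define the class. The remaining lists against alpha-like cells had medians, with all genes and then without hormone genes in the total, of -0.03 and 0.06 for immature and disallowed genes, -0.41 and 0.02 for hormone granules, -0.39 and -0.07 for MHC class I presentation, -0.03 and 0.03 for interferon genes, -0.12 and 0.17 for p53 and senescence, and -0.52 and -0.06 for immediate early genes. Except for hormone granules, the libraries differed in sign in each of these lists with all genes in the total. Immediate early genes had -0.10, -1.03, 0.40 and -0.94 in libraries 1 to 4, and p53 and senescence 0.11, -0.36, 0.18 and -0.44. Without hormone genes, hormone granules had -0.23, 0.25, -0.20 and 0.32. Islet autoantigens had -0.07 and 0.35, with 5 of 12 members higher and 4 lower in every library with all genes in the total, and proliferation had -0.03 and 0.00, both again with libraries that differed in sign. Of the immature genes, Rbp4 (-3.60) was lower in beta-like cells, and of the senescence genes Cdkn1a, an inhibitor of the cell cycle, was higher (1.73). Against endothelial-like cells, interferon genes had -2.29, -0.51, -2.45 and -0.85 in libraries 1 to 4, lower than every random list in libraries 1 and 3 and at percentiles 84.7 and 24.8 of random lists in libraries 2 and 4. Of 26 members, 20 were lower in every library, or 17 without hormone genes. Bst2 led them with a median of -3.73 (-5.10 to -2.37 over libraries), then Isg15 with -3.30 (-4.83 to -1.42). In endothelial-like cells Ins2 itself reached a median of 0.0618%, 1.68%, 0.0680% and 0.754% of each cell's UMIs in libraries 1 to 4, and 37235, 99009.8, 1519 and 58059 CPM of their summed UMIs. Alpha-like cells reached a median of 0.0786%, 1.35%, 0.0947% and 0.653% of UMIs from Ins2 in libraries 1 to 4. Delta-like cells reached 0.0547%, 1.01%, 0.0701% and 0.514%. The origin of these transcripts was not tested, and they shrink ratios of abundant beta-cell genes against each of these classes.

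**Figure D3:**
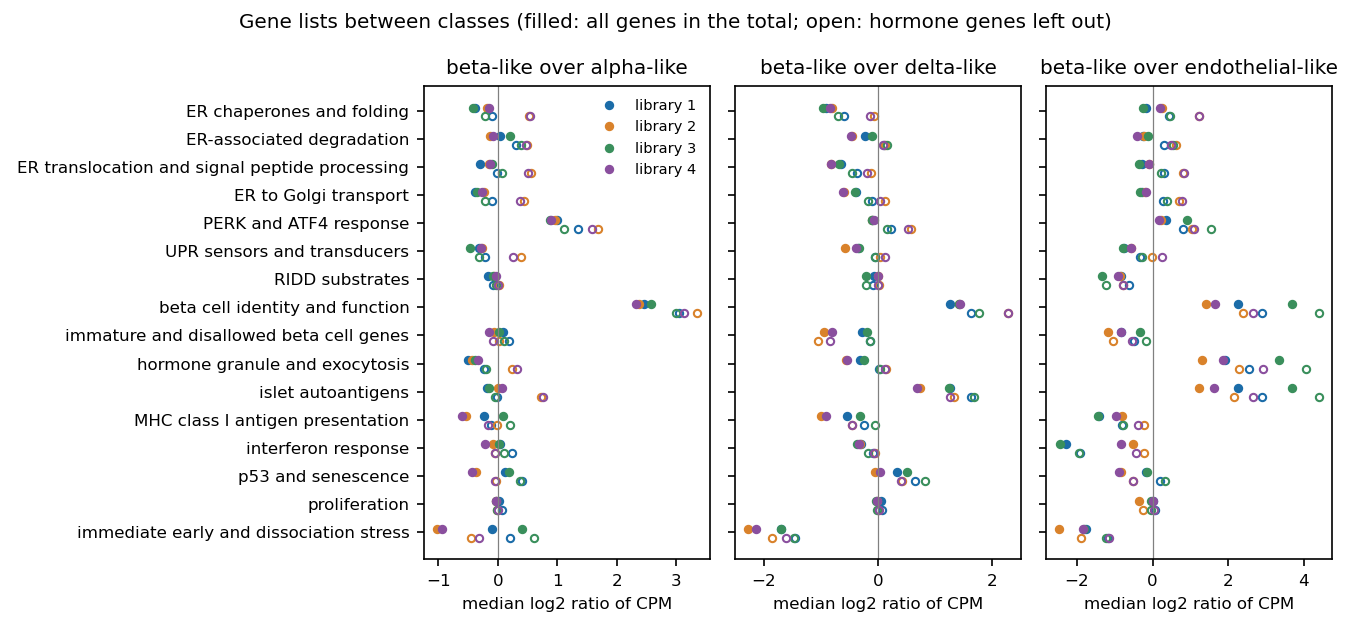
Points give each list's median log2 ratio of CPM in beta-like cells over another class for each library, with all genes (filled) or without hormone genes (open) in the total. The PERK and ATF4 list lies between 0.88 and 0.99 against alpha-like cells with all genes in the total.

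Across the libraries, 16 of 1162 genes at 100 CPM or more in beta-like cells had a range of at least 4-fold after 10 CPM was added to each level. The count was also 16 over these 1162 genes with hormone genes left out of the total, and 24 where the minimum of 100 CPM was applied on that scale too. Cck, a gut and brain peptide, stood at 456, 0.465, 384 and 0.516 CPM in libraries 1 to 4. Npy stood at 1029, 128.4, 889 and 125 CPM, the glutathione peroxidase Gpx3 at 277, 28.3, 336 and 28.9, and Txnip at 184, 25.2, 189 and 20.4. Lpl, at 17.5, 111, 20.1 and 95.02 CPM, and the metallothionein Mt2, at 297, 913, 315 and 1149 CPM, had their lowest values where Npy had its highest. Cck did not follow the clusters alone. It stood at 444 and 365 CPM in cluster 2 of libraries 1 and 3, at 641, 1.85, 432 and 0.811 in cluster 3 and at 44.1, 0.511, 439.8 and 0.299 in cluster 16 of libraries 1 to 4. Within cluster 3 and within cluster 16 it was thus higher in libraries 1 and 3 than in libraries 2 and 4. The range of Npy followed the clusters more closely. Npy stood at 1477 and 1163 CPM in cluster 2 of libraries 1 and 3, but at 98.5, 59.5, 317 and 98.1 in cluster 3 and at 18.5, 102.6, 77.4 and 76.8 in cluster 16 of libraries 1 to 4. Txnip in cluster 16 stood at 30.9, 29.1, 177 and 21.1 CPM, and at 172 and 168 CPM in cluster 2 of libraries 1 and 3. In cluster 3 it stood at 212, 56.2, 253 and 58.7 CPM, so within that cluster it was higher in libraries 1 and 3.

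Among the lists, the immediate early genes ranged most, at 0.66, -0.83, 0.54 and -0.52 log2 units around each gene's median over libraries. Interferon genes stood at 0.70, -0.25, 0.25 and -0.32, with 24 of 25 members highest in library 1. ER chaperones stood at -0.15, 0.15, -0.27 and 0.26, with 17 of 22 members highest in library 4. The median gene itself stood at 0.18, -0.21, 0.20 and -0.18, and relative to it the chaperones stood at -0.33, 0.36, -0.47 and 0.44. Dnajb9, a co-chaperone, stood at 91.0, 219, 90.3 and 243 CPM, Sdf2l1 at 92.1, 195, 86.4 and 223, and Hspa5 at 910.0, 925, 885 and 1022 CPM. In cluster 16, with 30 cells in library 1 and 40 in library 3, Dnajb9 stood at 203, 216, 108 and 246 CPM and Sdf2l1 at 192, 195, 122 and 235. In cluster 3, with 148, 148, 191 and 101 cells, Dnajb9 stood at 136, 204, 131 and 220 CPM and Sdf2l1 at 130, 170, 117 and 199. Both were thus lower in libraries 1 and 3 within cluster 3, whose Gcg was above 2% of UMIs in libraries 2 and 4. Cluster 2 of libraries 1 and 3 held Dnajb9 at 61.9 and 72.0 CPM and Sdf2l1 at 70.5 and 73.8. In delta-like cells the chaperone list covered a range of 0.55 log2 units, beside 0.54 in beta-like and 0.13 in alpha-like cells. Without hormone genes the ranges were 0.63, 1.01 and 0.13. The interferon list covered 1.03 in beta-like, 1.03 in delta-like, 0.69 in alpha-like and 2.88 in endothelial-like cells, and without hormone genes 0.97, 1.16, 0.79 and 2.89.

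**Figure D4:**
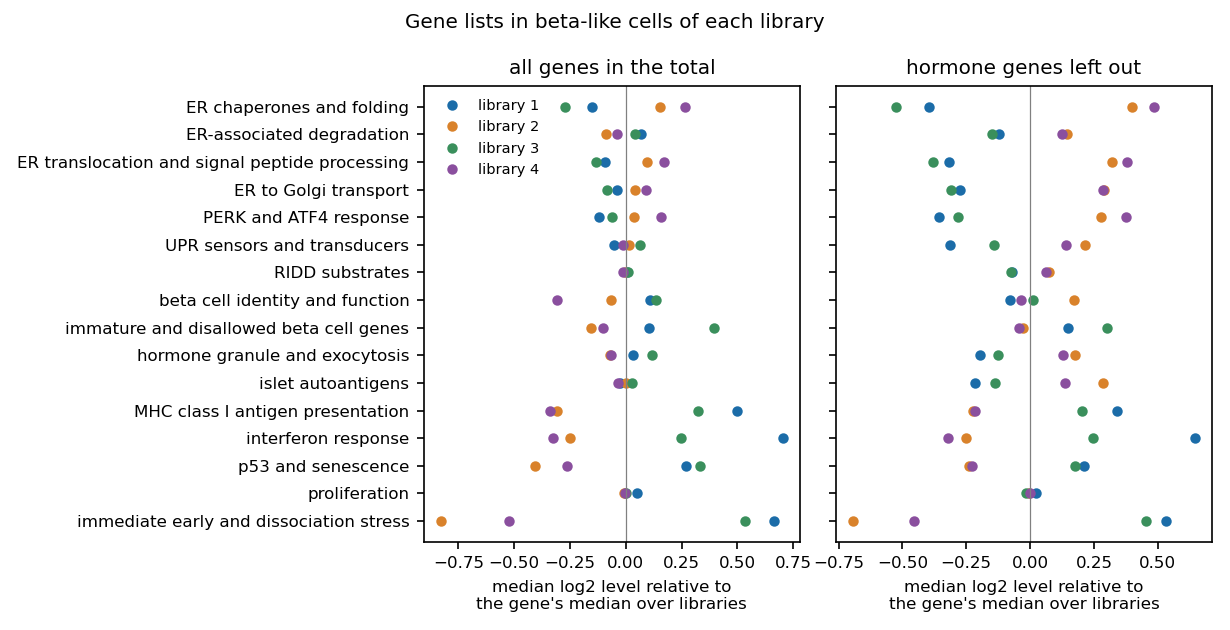
Points give each list's median log2 level in beta-like cells of a library relative to each gene's median over libraries, with all genes (left) or without hormone genes (right) in the total. ER chaperones lie between -0.27 in library 3 and 0.26 in library 4 with all genes in the total.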

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

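Signal was present in 7 clusters that no comparison used, because their cells stayed unnamed. Cluster 4, with 467 cells, was led by Ccl5, Ccr7 and Fscn1. Cluster 9, with 102 cells, was led by Jchain, Igkc and Mzb1, and held Xbp1 at 952 CPM in library 1 and 663 CPM in library 3. Cluster 15, with 55 cells, was led by the proteases Cma1 and Mcpt4. Cluster 24, with 39 cells, was led by Ube2c, Top2a and Mki67 against all other cells. Several hormones were abundant together in clusters 0, 12 and 19, with 368, 176 and 449 cells. Cluster 0 was led by Ppy and Pyy, markers of pancreatic polypeptide cells, and held 46, 147, 67 and 108 cells in libraries 1 to 4. Pancreatic polypeptide cells may therefore be among the unnamed cells.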

How the results depend on the processing

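Of 1216 values recomputed under alternatives, 1097 moved by less than their counting interval or 1 SD over libraries (counts of genes: 1.5 times). That SD is wide where libraries differ, so the 1097 do not show stable medians. Another 108 moved further, and 11 with the same sign in all 4 libraries as reported changed sign. Hormone genes left out of the total gave each of these 11 changes, since those genes take 40.6% to 58.0% of the total of beta-like cells. Where libraries differed in sign as reported, 23 further medians crossed 0, of which 6 with hormone genes left out. Medians over libraries against alpha-like cells then became 0.21 for ER chaperones, 0.29 for ER translocation, 0.13 for ER to Golgi transport, 0.016 for UPR sensors, 0.022 for hormone granules, 0.43 for ER-associated degradation (from -0.024) and 1.46 for PERK and ATF4. Chaperones, Golgi transport, UPR sensors and hormone granules stayed below 0 in libraries 1 and 3. With all genes, chaperones were -0.18 without library 1 or library 3 and -0.39 without library 2 or library 4. ER-associated degradation was also 0.019 with the mean of each cell's CPM and 0.036 without library 2 or library 4. Against delta-like cells they became 0.11 for ER-associated degradation, 0.37 for PERK and ATF4 and 0.077 for hormone granules, and against endothelial-like cells 0.52, 0.55 and 0.54 for ER-associated degradation, translocation and Golgi transport. Xbp1 in beta-like cells became 77.3, 226.6, 69.6 and 222.5 CPM, with a median of 149.9 in place of 70.4. With all genes that median was 45.7 without library 2 or 4 and 95.1 without library 1 or 3, each among the 1097. The ranges over libraries became 1.01 for chaperones, 0.29 for degradation, 0.76 for translocation, 0.60 for Golgi transport and 0.73 for PERK and ATF4. Other values moved with the cause not tested. The share of beta-like cells in library 2 became 62.4% with the stricter cell filter, 62.1% at Leiden resolution 0.5 and 63.2% without cells holding several hormones, which gave 60.1% in library 4. The mean of each cell's CPM gave Xbp1 at 100.2 and 101.6 CPM in libraries 2 and 4 and 0.98 for PERK and ATF4 against alpha-like cells, and a pseudocount of 1 gave 1.18. Leaving out each library gave 0.15 to 0.28 for the range of PERK and ATF4, the lowest without library 4. The count of genes with a 4-fold range rose from 16 to 26 with a pseudocount of 1, since low values are then shrunk less. Leaving out cells with several hormones or the highest doublet scores, and leaving out a library for the ranges and this count, were chosen after seeing the data. DESeq2, other tests of genotype and paired analysis were not run because no library is tied to a sample.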

Other observations

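Of the tests below, those on the cell filter and on UMIs per cell were set before their result was seen, and all others after it. Endothelial-like cells, whose interferon genes were looked at after their values were seen, held Isg15 at 668, 19.8, 438 and 32.9 CPM in libraries 1 to 4 and Cxcl10 at 186, 0.470, 53.4 and 1.27 CPM. Esm1 stood at 250.4, 1614, 247 and 2246 CPM in the same cells. In beta-like cells Isg15 stood at 16.9, 1.14, 5.72 and 1.14 CPM.

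Xbp1 in beta-like cells fell into 2 sets of values, 45.7 and 41.4 CPM in libraries 1 and 3 and 95.1 and 96.5 CPM in libraries 2 and 4. Cluster 3 parted the same way, at 76.4 and 68.3 CPM in libraries 1 and 3 and 107 and 105 CPM in libraries 2 and 4. In libraries 2 and 4 its Gcg was above 2% of UMIs. Cluster 16 did not part this way: it held 95.8 CPM in library 1 (30 cells), 95.9 in library 2, 67.7 in library 3 (40 cells) and 96.5 in library 4. Cluster 2, at 29.1 and 29.8 CPM, held 65.3% and 64.5% of beta-like cells in libraries 1 and 3. If hormone transcripts in the total made the gap between libraries in beta-like cells, leaving them out would end it. They took 58.0% and 56.6% of UMIs in libraries 2 and 4, and 40.9% and 40.6% in libraries 1 and 3. These shares fixed the outcome, since leaving hormone genes out could only widen the gap. Without them in the total the highest library was 3.26 times the lowest, so this scale does not make the gap. An effect on every cell of a library, such as depth or free RNA, would move Xbp1 in other endocrine cells. With all genes in the total, the highest library there was at most 1.14 times the lowest. Without hormone genes, Xbp1 ran from 167 to 191 CPM in alpha-like cells and from 203 to 236 CPM in delta-like cells. Outside the endocrine cells Xbp1 ranged in some classes only. Endothelial-like cells held 289, 115, 318 and 98.7 CPM in libraries 1 to 4. Ductal-like cells held 262, 107, 234 and 135 CPM, with 29 cells in library 2 and 10 in library 4. Hormone transcripts took 2.00%, 12.3%, 0.424% and 19.0% of the UMIs of these ductal-like cells. Macrophage-like cells held 74.3, 77.3, 75.0 and 84.1 CPM. Fibroblast-like cells held 85.3, 79.7, 99.3 and 107 CPM, with 11 cells in library 2 and 9 in library 4. An effect on some classes thus stays open. Leaving out cells with several hormones left a ratio of 2.35. Genotype stays open and was not tested, since no library is tied to a sample, as do differences between animals or preparations. The make-up of beta-like cells by cluster cannot be told apart from a difference between libraries. Clusters were formed on the pooled cells with no correction for library, and cluster 2 held 0 cells of library 2 and 4 of library 4.

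The share of B cell-like cells ranged from 0.0264% to 18.5%. A lower share of beta-like cells would raise every other class alike, but alpha-like cells as a share of all cells that were not beta-like were 8.75%, 39.2%, 11.7% and 46.9% in libraries 1 to 4, a ratio of 5.35. The cell filter does not account for it: among all deposited barcodes, those with at least 2 UMIs of the B cell gene Cd79a made up 19.2%, 1.16%, 15.1% and 0.642%, a ratio of 29.9. Genotype, infiltration of the islets and carry-over of tissue around hand-picked islets stay open and were not tested.

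Within libraries 1 and 3, the only ones with 50 cells or more of both, beta-like cluster 3 held more Xbp1 than cluster 2. Cluster 2 held 29.1 and 29.8 CPM and cluster 3 held 76.4 and 68.3 CPM, although Xbp1 was left out of the clustering genes. Doublets with alpha-like or delta-like cells would carry Gcg and Sst, whose median share in cluster 3 of these libraries was at most 0.0245% of UMIs. A median cannot show doublets in a minority of cells. Summed over cluster 3, Gcg stood at 2889 and 3523 CPM and Sst at 1092 and 719 CPM in libraries 1 and 3. Such doublets are thus not typical of cluster 3 cells, but a smaller part of them stays open. Doublets with other classes were not tested. Among cells with at least 20000 UMIs, and without hormone genes in the total, cluster 3 held 3.56 and 3.16 times the Xbp1 of cluster 2, so a lower depth does not account for it. A mixture of cells in different states, or with and without deletion, may underlie the 3.16-fold gap, and neither was tested.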
